A study of Homo sapiens with 20 samples.

How the data were processed

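Gene expression was measured in human mammary epithelial cells on 20 arrays that form 12 groups in 5 experiments, numbered I, II, IV, VIII and XI in the labels. Experiment I held untransduced cells at passage 9 and passage 13 and cells labelled hTERT, the catalytic subunit of telomerase, with 2 arrays each. Experiment II held untransduced cells, cells with the empty retroviral vector LXSN and cells labelled hTERT, with 2 arrays each. Experiment IV held cells with the empty vector BABE and cells labelled hTERT, with 2 arrays each, and experiments VIII and XI held 1 array of each of these arms. The labels number the replicates but do not state whether they were separate cultures, so the p-values measure only the spread between these arrays. The labels give a passage only for the untransduced cells of experiment I.

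The authors deposited 1 table of intensity values, on a linear scale with 1 decimal, for 5119 probes. The scanner software and the scaling are not given in the sources used here. Between 0 and 11.3% of the values of an array were negative, as in differences of matched and mismatched probes, and array means lay between 953 and 1058. The deposited medians of replicates 1 and 2 were 461 and 452 at passage 9, 465 and 482 at passage 13, and 405 and 451 for hTERT in experiment I. In experiment II they were 454 and 449.9 for untransduced cells, 549 and 435 for LXSN, and 432 and 441 for hTERT. In experiment IV they were 501 and 332 for BABE, and 301 and 338 for hTERT. The medians were 459 for BABE and 409 for hTERT in experiment VIII, and 408 and 419 in experiment XI. Array means were similar, but whether the authors scaled to a mean, and whether any centring was done, stays unknown. Passage 9 replicate 1 had no negative value, and its values ran from 10 to 6699.7, whereas all other arrays exceeded both bounds. The probes in the table were thus limited by the values of that array, and genes that were dark or very bright in it are not analysed here.

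Trimmed means of the arrays (2% at each end) ranged from 822 to 971, so the values were quantile normalized across the 20 arrays on the linear scale. Values under a floor of 58.3, the median size of the negative values after normalization, were set to it, and log2 was taken. Differences are given as bounds where all arrays of an arm lay at the floor, and the text names the passing genes whose dimmer arm averaged under 2 times the floor, a check made after the data were seen. A probe was tested when at least 3 arrays exceeded 2 times the floor, which left 4592 probes for 3520 genes. The 33 AFFX control probes were not tested. Of the probes in the table, 4190 had 1 gene symbol, 218 had several and 711 had none. Of those with 1 symbol, 4189 matched the RefSeq gene table and 0 symbols needed updating. Probes without a single symbol are named by their probe identifier. After the floor, 8.01% of the values of tested probes lay at it. The number of arrays limits the precision.

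The comparison of hTERT with empty vector used the 12 arrays of experiments II, IV, VIII and XI, in limma 3.58.1 under R 4.3.3, with the experiment as a fixed block and moderated variances. It had 7 residual degrees of freedom and 3.10 prior degrees of freedom. All other comparisons were contrasts of group means in a limma fit of all 20 arrays with 8 residual degrees of freedom, in which groups with 1 array borrow the spread of the replicated groups. A moderated F test asked whether the hTERT change differed between the experiments. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Of 28 gene lists, 26 with at least 5 tested genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists within a comparison. Each gene entered by its probe with the highest mean. Beside the count of list members past the threshold over all probes stands the count adjusted over the list alone.

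Genes were named by a rule. For hTERT against empty vector these were the 12 largest rises and the 12 largest falls among probes with 1 symbol that passed and had the same sign in all 4 experiments, with the probe of smallest p for each gene. For every other comparison they were the 8 largest in each direction past the threshold whose groups did not overlap, filled by smallest p where fewer passed. For each gene list, up to 4 members with the smallest p were taken in the first comparison and in that of the passages. TERT, EGFR, CDKN2A and MYC were always named. CDKN1A belonged to the same part of the rule, but no tested probe named it alone. An item of the rule and a gene list are not reported here. Other genes in the text were chosen after their values were seen. The samples, comparisons, tests, lists, alternatives and this rule were fixed before the data were examined, except the alternatives, the TFRC controls and the larger simulated changes said below to have been chosen later, the list of amino acid response genes, and the tests so named in the closing section.

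Alternatives covered other scalings (trimmed mean, median, values as deposited), a lower and a higher floor, a generalized logarithm, no filter and a stricter filter of 4 times the floor, each replicate left out, each experiment left out, the replicate number as a block, replicates averaged, another variance model, the mean of all probes of a gene in the lists, a rule of at least 2-fold in all 4 experiments, untransduced and vector controls together, and only the arrays of the experiment at hand. Alternatives added after seeing the data left out the vector arrays that stood apart, took passage 9 from replicate 2, used bright probes with a mean above 8 times the floor, or crossed the replicate numbers. The vector arrays that stood apart were LXSN replicate 1, with 8.89% negative values and a median correlation of 0.788 with the other arrays, and BABE replicate 1 of experiment IV, with 11.3% and 0.775. Replicates correlated between 0.855 and 0.942 across probes, and 0 pairs of arrays were identical.

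RNA quality was to be read from 3' and 5' control probes of GAPDH and ACTB, of which the table held only probe sets with the suffix st, so the control probes of TFRC were taken instead, a choice made after the table was seen. The log2 ratio of 3' to 5' signal differed between hTERT and vector by a mean of −0.30 over experiments II, VIII and XI (exact permutation test within experiments, two-sided, p = 0.833, where the smallest possible p is 0.0833). This mean joined opposite differences. The ratio was 0.96 for hTERT and 2.41 for BABE in experiment VIII, and 2.36 and 1.94 in experiment XI. In experiment II it was 1.54 and 1.84 for hTERT, and 1.02 and 2.10 for LXSN. The test thus does not show that the arms match in RNA quality. Experiment IV was left out, also after its values were seen, because TFRC was dim there. The share of negative values differed by −0.496 percentage points (exact permutation test, two-sided, p = 0.417).

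The fits were tested on simulated data with 4592 probes, of which 200 were changed. Noise was drawn independently for each array, with no term for shared cultures. For hTERT against empty vector the simulated change was equal in all experiments. The shares below therefore do not hold if the replicates were not separate cultures or if the change differs between experiments. For hTERT against empty vector, 58% of changes of 1 and 91% of changes of 2 on the log2 scale were recovered, with 3.25% false calls. For passage 13 against passage 9 these shares were 8% and 63%, with 5.33% false calls. They were 16% and 72% for hTERT against passage 13, with 9.28% false calls, and 10% and 76% for hTERT against passage 9, with 5.49%. They were 8% and 61% both for LXSN and for hTERT against untransduced cells, with 10.4% and 4.17% false calls, so the false calls exceeded 5% in several comparisons. The F test recovered 0 of 100 changes of 1 and 0 of 100 changes of 2 confined to experiment II. Larger changes were simulated only after this was seen. With sizes of 2 and 4 mixed, the F test recovered 28 and 74 of 100 with 3.77% false calls, and with sizes of 3 and 6 it recovered 62 and 73 of 100 with 5.59%. A simulated list with a known shift passed camera. Figures were drawn with matplotlib 3.10.9 under Python 3.11.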

Results

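Expression was compared between human mammary epithelial cells labelled hTERT, which denotes the catalytic subunit of telomerase, and cells with an empty retroviral vector or no vector. There were 20 arrays in 12 groups: 8 groups of 2 arrays and 4 groups, those of experiments VIII and XI, of 1 array. All values are log2 differences of normalized intensity with the standard error of the limma fit, and n is the number of arrays in each arm. The number of arrays limits the precision.

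The TERT probe (AF015950_at), which reads the gene that the labels name, was bright in the cells labelled hTERT of experiments I and II and not in those of the other experiments. Its normalized intensity was 2096 and 2359 on the hTERT arrays of experiment I, and 3824 and 2283 on those of experiment II. On the arrays labelled hTERT of experiments IV, VIII and XI it was −715.8, −309.6, −250.7 and −351.5, under the floor of 58.3. Passage 9 gave 79.7 and 126, and all other controls lay under the floor. For experiments IV, VIII and XI the text therefore speaks of arrays labelled hTERT.

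**Figure D1:**
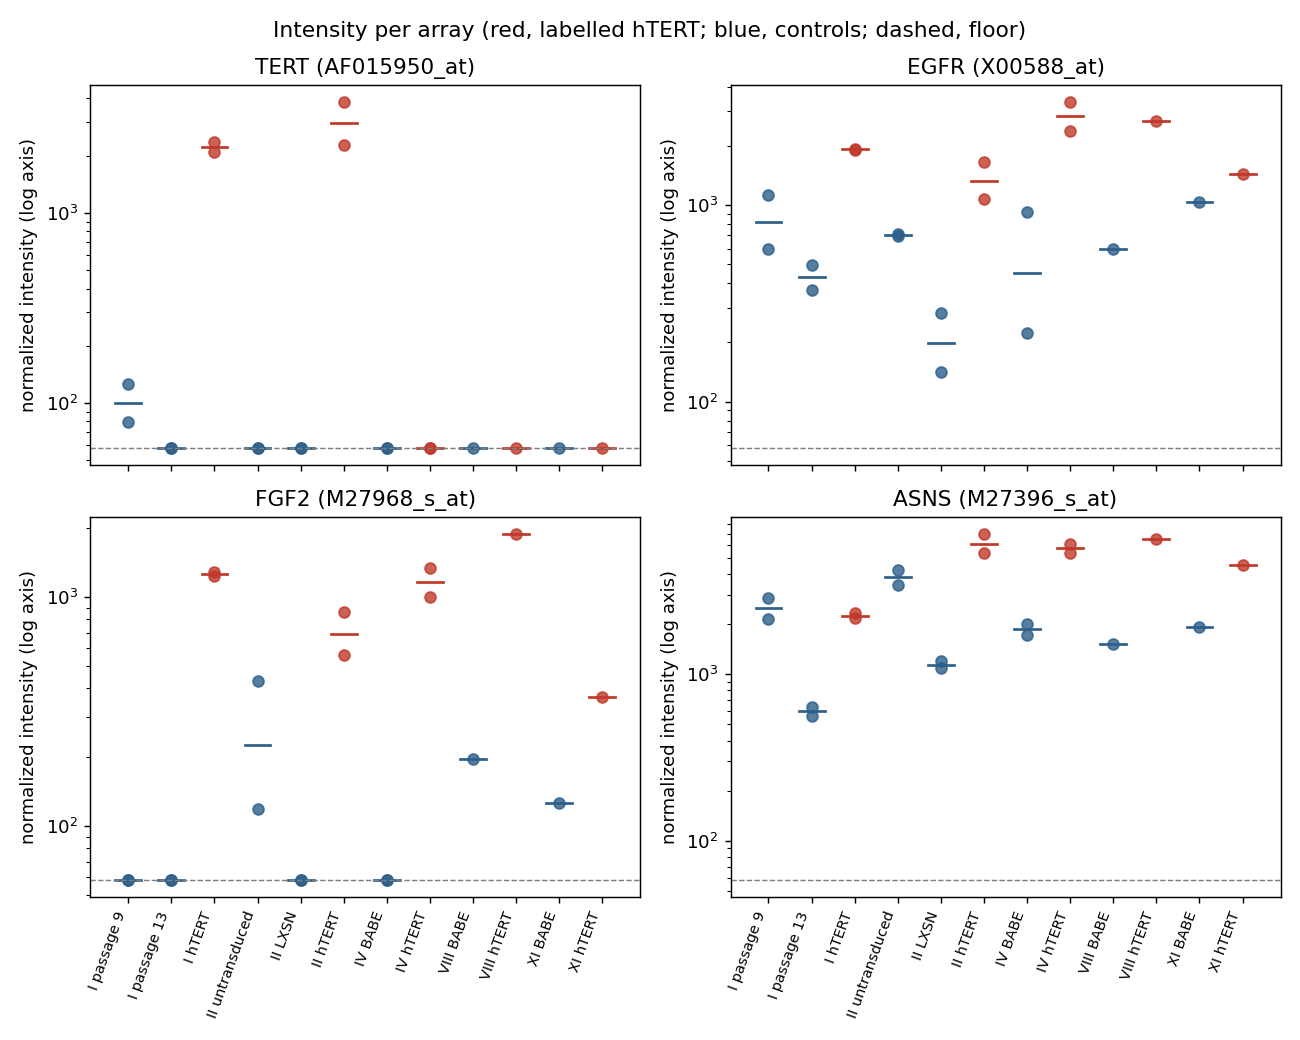
Normalized intensity (log axis) of TERT, EGFR, FGF2 and ASNS in each of the 12 groups, with a point per array, a bar at the geometric mean and a dashed line at the floor of 58.3. TERT stands above the other groups in the hTERT arrays of experiments I and II, and lies at the floor in the arrays labelled hTERT of experiments IV, VIII and XI.

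The first comparison asked how arrays labelled hTERT differed from empty vector within experiments II, IV, VIII and XI (n = 6 and 6). ATF3, a transcription factor induced by stress, rose by 3.49 ± 0.35, and FGF2, a fibroblast growth factor, rose by 3.43 ± 0.34. EGFR, the receptor for epidermal growth factor, rose 4.70-fold (2.23 ± 0.42), from 223 and 916 to 3329 and 2388 in experiment IV and from 1033 to 1434 in experiment XI. C3, a complement protein, fell by 2.91 ± 0.53, and SERPINB3 and SPRR1A, which are made in squamous epithelium, fell by 2.61 ± 0.48 and 2.65 ± 0.63. The dimmer arm averaged under 2 times the floor for ATF3, FGF2 and SERPINB3, so their sizes depend on the floor: with a lower and a higher floor FGF2 gave 3.91 and 2.76. Of 4592 probes, 316 passed, 194 higher and 122 lower, of which 296 had the same sign in all 4 experiments. Passing the test favours probes with a shared sign, so the 296 are no separate evidence. The same sign in all 4 was seen for 29.0% of the tested probes. Random signs would give 12.5% on average, but the spread of that share was not estimated, and probes move together. The passing probes with 1 symbol numbered 267, for 264 genes.

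Among the largest rises were also COL11A1 (3.48 ± 0.77), a fibrillar collagen whose other probe gave −0.53, FOSL1 (3.10 ± 0.58), an AP-1 subunit, and UFM1 (2.91 ± 0.40), a ubiquitin-like modifier. CTH, an enzyme of cysteine synthesis, rose by 2.73 ± 0.29, and NNMT, which methylates nicotinamide, by 2.52 ± 0.53. PHLDA1 rose by 2.46 ± 0.43, VEGFA, a growth factor of blood vessels, by 2.13 ± 0.31, CXCL2, a chemokine, by 2.13 ± 0.22, and AXL, a receptor tyrosine kinase, by 2.07 ± 0.26. Adjusted p for these 12 rises lay between 0.00118 and 0.0279. In experiment II, CTH and VEGFA gave 3.24 (a bound) and 2.75 for hTERT against LXSN, but 1.12 and 0.60 against untransduced cells. LXSN itself gave −2.12 (a bound) and −2.15 against untransduced cells, and NNMT was also lower there. For these genes the rise in experiment II thus lay at least partly in a lower LXSN arm. UFM1 passed as higher against untransduced cells too. Experiments IV, VIII and XI held no untransduced cells. Among the largest falls were OAS1 (−2.29 ± 0.48), an interferon-induced enzyme, PLAT (−2.28 ± 0.44), the tissue plasminogen activator, and PI3 (−2.27 ± 0.38), an elastase inhibitor of squamous cells. NEFL, a neurofilament protein, fell by 2.21 ± 0.21, while its other probes gave −0.62 and −0.48. STC1, a secreted glycoprotein, fell by 2.18 ± 0.27, SAA1, an acute phase protein, by 2.06 ± 0.26, and IDI1, an enzyme of isoprenoid synthesis, by 1.93 ± 0.33. GRK5, a receptor kinase, fell by 1.78 ± 0.32, and IVL, a protein of the cornified envelope, by 1.74 ± 0.29. Adjusted p for these 12 falls lay between 0.00118 and 0.0342. The sizes for FOSL1, UFM1, CTH, AXL, OAS1, STC1 and GRK5 depend on the floor in the same way, with 2.71 and 1.41 for AXL and −2.42 and −1.03 for GRK5 with a lower and a higher floor. TERT, at the floor in both arms of experiments IV, VIII and XI, did not pass (1.89 ± 0.86, adjusted p = 0.211), nor did CDKN2A, a cell cycle inhibitor (0.93 ± 0.27, 0.0708), nor either probe of MYC (0.54 ± 0.20, 0.135, and 1.01 ± 0.35, 0.111).

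Of the 26 gene lists, 7 passed camera and none passed with an estimated correlation, where the smallest adjusted p was 0.322. Growth factors and their receptors were shifted up: of 22 genes, 5 rose (FGF2, AXL, VEGFA, EGFR and EPHA2, the last by 0.94 ± 0.18), 2 fell (FGFR3 by 1.04 ± 0.21 and FGF1 by 0.70 ± 0.18, which did not pass with a lower or a higher floor), and the others did not pass (adjusted p = 0.0176, and adjusted p = 0.322 with an estimated correlation). Adjusted over the list alone, 8 were higher and 2 lower. In experiment II this list passed neither for hTERT nor for LXSN against untransduced cells. Of 21 genes of MYC targets and ribosome biogenesis, 4 rose, also adjusted over the list alone: SHMT2, a serine hydroxymethyltransferase (1.29 ± 0.29), GART and IMPDH2, enzymes of purine synthesis (1.21 ± 0.31 and 0.76 ± 0.20), and EIF2S1, a translation factor (0.92 ± 0.17). The adjusted p was 0.0215, with adjusted p = 0.484 with an estimated correlation, and 0.147 without the 2 vector arrays that stood apart from the rest.

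Squamous differentiation genes were shifted down: of 20 genes, 4 fell and 0 rose, also adjusted over the list alone, namely IVL, PI3, SERPINB3 and SPRR1A (adjusted p = 1.09e-04, and adjusted p = 0.322 with an estimated correlation). Of 27 interferon response genes, 4 fell, and 6 adjusted over the list alone. They were OAS1, the membrane protein BST2 (−1.48 ± 0.34), IFI44 (−1.48 ± 0.36) and IFI44L (−1.29 ± 0.33), with an adjusted p of 0.0142 and adjusted p = 0.544 with an estimated correlation. In experiment II, SERPINB3 and OAS1 gave −4.30 and −4.12 for hTERT against LXSN, but 3.68 and 3.52 for LXSN against untransduced cells. Neither the squamous nor the interferon list passed for hTERT against untransduced cells. There the falls thus lay at least partly in a higher LXSN arm, and experiments IV, VIII and XI held no untransduced cells. Of 18 fibroblast markers, FAP, a cell surface protease, fell by 1.66 ± 0.17, and 5 fell adjusted over the list alone (adjusted p = 0.0134, and adjusted p = 0.322 with an estimated correlation). Of 13 genes of cholesterol and lipid synthesis, 3 fell: IDI1, ACLY, which makes acetyl-CoA (−1.32 ± 0.30), and NSDHL (−1.04 ± 0.18). Adjusted over the list alone 6 were lower and 1 higher, with an adjusted p of 0.0215 and adjusted p = 0.484 with an estimated correlation. Of 25 genes of oxidative stress and metallothioneins, catalase (CAT) fell by 1.37 ± 0.21 and HMOX1, a haem oxygenase, by 1.27 ± 0.33, also adjusted over the list alone (adjusted p = 0.0301, and adjusted p = 0.325 with an estimated correlation).

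The other lists did not pass camera, though members did. Of 25 immediate early genes 4 rose, ATF3, FOSL1, DUSP1 (1.17 ± 0.20) and ZFP36 (0.74 ± 0.16), and 2 fell, CCN2 (−1.48 ± 0.24) and DUSP6 (−0.74 ± 0.17), with 5 higher and 4 lower adjusted over the list alone (adjusted p = 0.365). Of 23 genes of extracellular matrix and proteolysis 1 rose, TNC, a matrix glycoprotein (2.07 ± 0.23), and 4 fell, PLAT, CCN2, ITGA2 (−0.93 ± 0.22) and MMP7, a matrix protease that lay at the floor on all arrays labelled hTERT and in both arms of experiment XI, counts that were the same adjusted over the list alone (adjusted p = 0.0693). Of 16 secreted inflammatory factors CXCL2, CXCL3 (1.42 ± 0.29) and PTGS2 (1.45 ± 0.28) rose, IL1RN, an interleukin 1 antagonist, fell by 1.73 ± 0.25, and TNFSF10, a ligand of death receptors, was at least 2.25-fold lower, also adjusted over the list alone (adjusted p = 0.844). Of 19 genes of IGF-binding proteins and the TGF-beta family BMP2 (2.02 ± 0.24), GDF15 (1.84 ± 0.32) and SMAD7 (0.87 ± 0.19) rose and LTBP1 fell by 0.98 ± 0.21, with 4 and 4 adjusted over the list alone (adjusted p = 0.844). Of 15 NF-kappaB targets 3 rose, also adjusted over the list alone: NFKB1 (0.69 ± 0.16), NFKB2 (1.16 ± 0.29) and REL (0.85 ± 0.21), subunits of the factor itself (adjusted p = 0.409). The vector arm averaged under 2 times the floor for BMP2 and REL, and REL did not pass with a higher floor.

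Among 20 genes of the G1 engine E2F4 (2.00 ± 0.47), E2F5 (0.72 ± 0.15) and CCNH (0.89 ± 0.21) rose, and 3 were higher and 1 lower adjusted over the list alone (adjusted p = 0.844). Of 24 mitosis genes CDC20 (1.21 ± 0.30) and HMGB2 (1.09 ± 0.26) rose, also adjusted over the list alone (adjusted p = 0.256), and of 31 DNA replication genes CDC6 rose by 1.75 ± 0.45, with 0 adjusted over the list alone (limma, 1 over all probes; adjusted p of the list 0.844). Of 17 heat shock and unfolded protein genes ASNS, asparagine synthetase (1.90 ± 0.20), and XBP1 (1.59 ± 0.19) rose and DNAJA1 fell by 1.15 ± 0.25, with 4 and 3 adjusted over the list alone (adjusted p = 0.936). Of 9 luminal markers XBP1 rose, and 3 were higher adjusted over the list alone (adjusted p = 0.844). Of 9 basal markers MYLK, a myosin kinase, fell by 1.12 ± 0.25, also adjusted over the list alone (adjusted p = 0.844). Of 22 apoptosis genes TNFSF10 and CASP1 (−1.27 ± 0.28) were lower, and 3 adjusted over the list alone (adjusted p = 0.936). In the lists of MHC genes (11, adjusted p = 0.844), endothelial markers (9, 0.619), leukocyte markers (13, 0.365), oxidative phosphorylation (27, 0.936), glycolysis (10, 0.433) and telomere maintenance (17, 0.936), limma passed 0 genes over all probes, whereas 1106 of all probes had an unadjusted p under 0.05. The 3 adipocyte markers gave −0.75 (ADIPOQ), 1.10 (PPARG) and −0.46 (LEP), and the 4 ribosomal proteins −0.35 (RPS25), −0.13 (RPS27), −0.02 (RPS15) and −0.02 (RPL24), none past the threshold. The median and the mean differed in sign for the lists of IGF-binding proteins, secreted inflammatory factors, MHC genes, basal markers, luminal markers, heat shock genes and apoptosis genes. The test of the telomere list was downward while its median (0.01) and mean (0.11) were positive.

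The count rested on few arrays and experiments: without experiment II limma passed 1 probe, without experiment IV 0 (832 at an unadjusted p under 0.05), without experiment VIII 133, and with the replicates averaged first 1. Without the vector arrays that stood apart, LXSN replicate 1 and BABE replicate 1 of experiment IV, 146 probes passed, 128 of them shared, and the squamous, interferon, fibroblast, cholesterol, oxidative stress and growth factor lists passed camera, as did that of extracellular matrix and proteolysis, downward (adjusted p = 0.0311), each with adjusted p = 0.440 with an estimated correlation. The cholesterol and oxidative stress lists did not pass with another scaling, nor without LXSN replicate 2, BABE replicate 2 of experiment IV or either array of experiment VIII, nor the MYC list without replicate 1 of hTERT or LXSN in experiment II, nor the oxidative stress list without that hTERT array, nor the interferon list without experiment II.

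**Figure D2:**
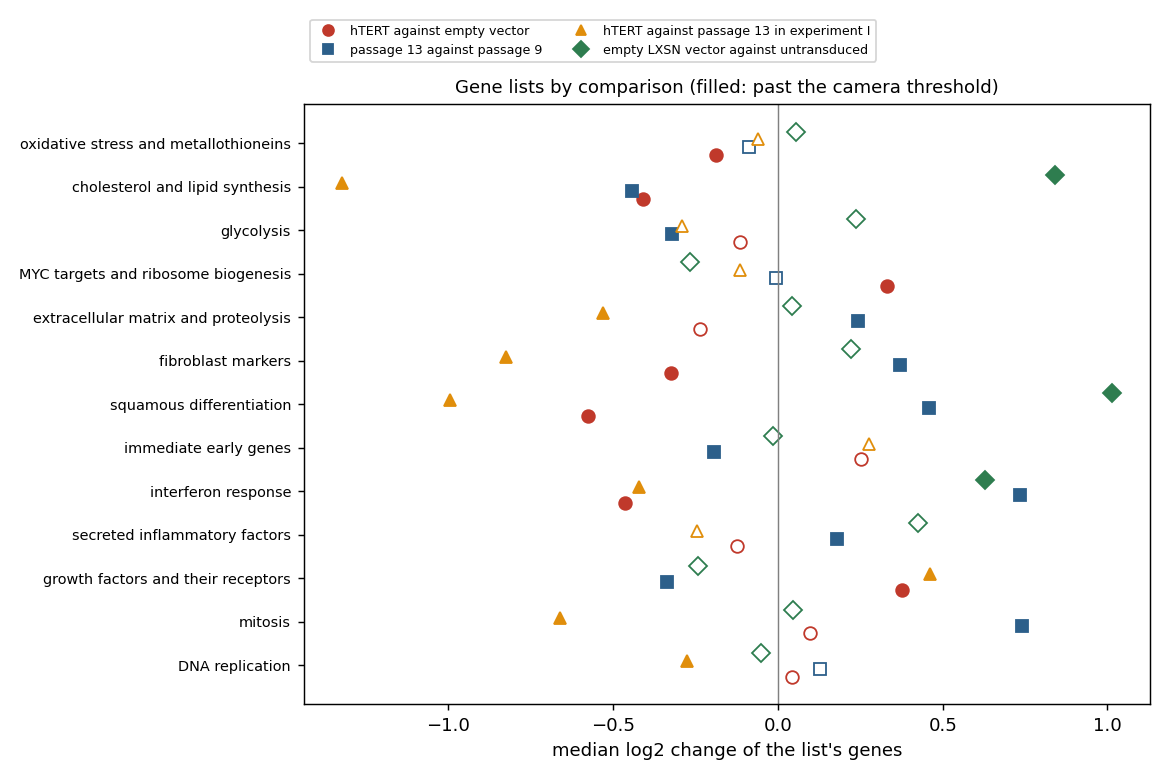
Median log2 difference of each gene list that passed camera in at least 1 of 4 comparisons, filled where it passed. The interferon and squamous lists lie below 0 for arrays labelled hTERT against empty vector and above 0 for passage 13 against passage 9. The cholesterol and lipid list lies below 0 in both.

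The second comparison asked what changed between passage 9 and passage 13 in untransduced cells of experiment I (n = 2 and 2). C3 rose by 4.62 ± 0.34, OAS1 by 3.76 ± 0.52, PLAT by 3.43 ± 0.49 and KRT13, a keratin of stratified epithelium, by 3.28 ± 0.64. IL18, a cytokine, rose by 3.05 ± 0.36 and SAA1 by 2.78 ± 0.25, while TCN1, a vitamin B12 binder, was at least 14.7-fold and MMP7 at least 6.37-fold higher. FOSL2, an AP-1 subunit, fell by 3.42 ± 0.50, ENO2, an enolase, by 2.80 ± 0.47, PTGS2, a prostaglandin synthase, by 2.45 ± 0.44, ASNS by 2.05 ± 0.24 and PDE7A, a phosphodiesterase, by 1.87 ± 0.38. THBS3 was at least 6.05-fold lower, BMAL1, a clock factor, at least 5.23-fold, with its other probe at −1.20, and IL13RA2, a decoy receptor, at least 5.15-fold. The dimmer arm averaged under 2 times the floor for OAS1, FOSL2, ENO2 and PDE7A, so their sizes depend on the floor, and ENO2 did not pass with a lower floor, nor PDE7A with a lower or a higher one. Of the 4592 probes 46 passed, 32 higher and 14 lower.

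Of 26 lists 10 passed camera, and 3 of them also with an estimated correlation. Mitosis genes were shifted up (adjusted p = 1.75e-11, and 0.0297 with an estimated correlation): of 24 genes CDK1, the mitotic kinase, was at least 4.13-fold higher, CDC25B, which activates it, rose by 1.69 ± 0.28, and 9 were higher adjusted over the list alone. Interferon response genes were shifted up (3.10e-12, and 0.00139 with an estimated correlation): of 27 genes 4 rose, OAS1, BST2 (2.33 ± 0.39), IFI44 (2.09 ± 0.24) and MX1 (1.52 ± 0.23), and 9 adjusted over the list alone. Squamous differentiation genes were shifted up (7.81e-05, and 0.0166 with an estimated correlation): of 20 genes KRT13 and PI3 (1.52 ± 0.29) rose, and 5 adjusted over the list alone. Of 16 secreted inflammatory factors IL18 and CXCL1, a chemokine (1.46 ± 0.28), rose, and 4 were higher and 1 lower adjusted over the list alone (0.0152, and adjusted p = 0.128 with an estimated correlation). Of 23 genes of extracellular matrix and proteolysis PLAT and MMP7 rose and TNC fell by 1.19 ± 0.24, with 4 and 1 adjusted over the list alone (0.0163, and adjusted p = 0.150 with an estimated correlation). Of 18 fibroblast markers FAP rose by 2.44 ± 0.20, also adjusted over the list alone (0.0163, and adjusted p = 0.164 with an estimated correlation).

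Shifted down were 13 genes of cholesterol and lipid synthesis (0.00383, and adjusted p = 0.232 with an estimated correlation), 25 immediate early genes (0.0163, and adjusted p = 0.212 with an estimated correlation), 22 growth factors and receptors (0.0174, and adjusted p = 0.164 with an estimated correlation) and 10 glycolysis genes (0.0388, and adjusted p = 0.150 with an estimated correlation). Of the immediate early genes FOSL2 fell, with 5 lower and 1 higher adjusted over the list alone, and of the glycolysis genes ENO2 fell, also adjusted over the list alone. By limma 0 members passed in the cholesterol and growth factor lists, also adjusted over the list alone, while 409 of all probes had an unadjusted p under 0.05. EGFR (−0.93 ± 0.59, adjusted p = 0.814), CDKN2A (0.22 ± 0.36, 1) and MYC (−0.21 ± 0.28 and −0.16 ± 0.53, both 1) did not pass, nor did TERT, which lay at the floor at passage 13 (0.348). Leaving out passage 13 replicate 1 gave 22 probes, passage 13 replicate 2 gave 23, and passage 9 replicate 1 gave 15. Without passage 9 replicate 1, the array that limited the table, the lists of growth factors (adjusted p = 0.125), immediate early genes (0.125) and fibroblast markers (0.0710) did not pass camera. The growth factor, immediate early and matrix lists did not pass without passage 13 replicate 1, the fibroblast and glycolysis lists without passage 13 replicate 2, and the glycolysis list without passage 9 replicate 2.

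**Figure D3:**
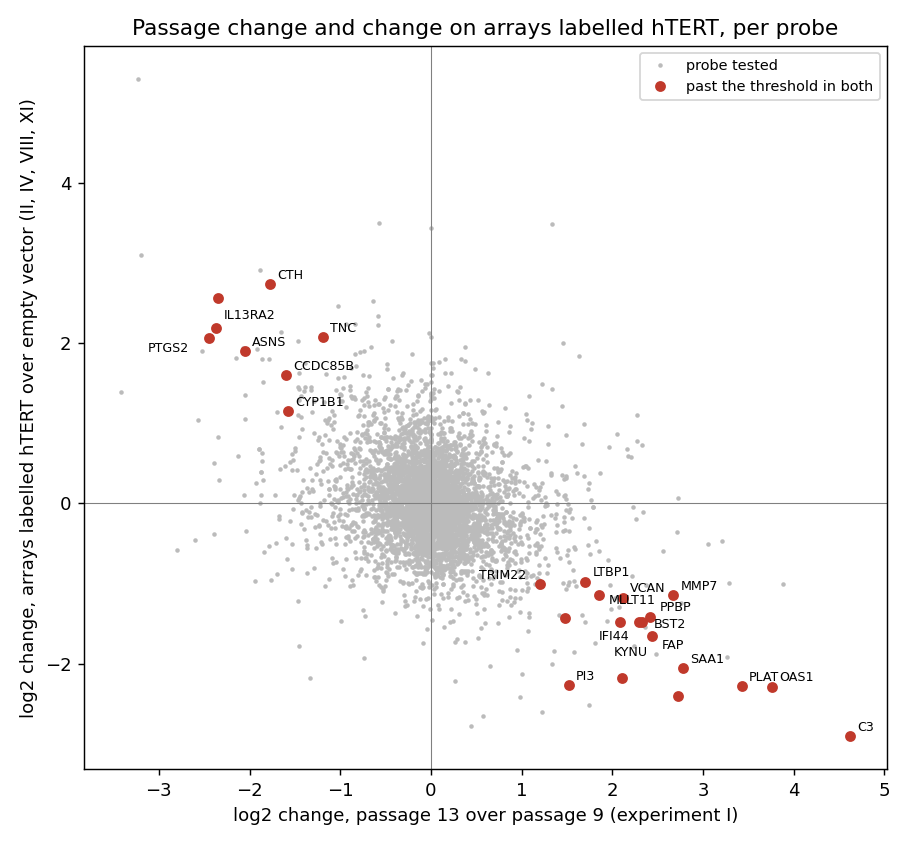
Log2 difference of arrays labelled hTERT against empty vector (vertical axis) plotted against that of passage 13 against passage 9 (horizontal axis), with a point per probe, those that passed in both in red, named where they have 1 gene symbol. Of 46 probes that passed with passage, 39 had the opposite sign on arrays labelled hTERT.

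The third comparison set hTERT cells of experiment I against untransduced cells of passage 13 (n = 2 and 2), with the passage of the hTERT cells not stated. TERT was at least 38.2-fold, IL13RA2 at least 35.2-fold, FGF2 at least 21.7-fold, SNRPC, a splicing protein, at least 20.2-fold and PIM1, a kinase whose other probe gave −0.29, at least 15.4-fold higher. UFM1 rose by 4.34 ± 0.48, ATF3 by 4.26 ± 0.59, SH3BGR by 3.93 ± 0.55 and EGFR by 2.16 ± 0.59. C3 was at least 117-fold, PLAT at least 61.2-fold, CCDC106 at least 27.2-fold, SLC25A1, the mitochondrial citrate carrier, at least 25.7-fold and the histone gene H2BC6 at least 25.1-fold lower. LTBP1, which binds TGF-beta, fell by 4.68 ± 0.27, TCTA by 4.36 ± 0.95 and FAP by 4.22 ± 0.20. The dimmer arm averaged under 2 times the floor for UFM1, ATF3, SH3BGR, LTBP1, TCTA and FAP, so their sizes depend on the floor, with −4.72 and −3.70 for LTBP1 with a lower and a higher floor. Of the 4592 probes 491 passed, 255 higher and 236 lower. CDKN2A (0.79 ± 0.36, adjusted p = 0.216) and MYC (0.14 ± 0.28, 0.835, and 0.03 ± 0.53, 0.995) did not pass.

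Of 26 lists 8 passed, and only the squamous list also with an estimated correlation. Of 20 squamous differentiation genes 8 fell, such as PI3 (−2.27 ± 0.29) and IVL (−2.49 ± 0.41), and 1 rose, KRT10 (0.97 ± 0.23), with 10 and 1 adjusted over the list alone (4.23e-04, and 0.0496 with an estimated correlation). Of 31 DNA replication genes 7 fell, among them MCM7 (−3.56 ± 0.54) and MCM6 (−1.34 ± 0.25), parts of the replicative helicase, and TYMS, thymidylate synthase (−1.47 ± 0.32), with 9 adjusted over the list alone (0.00501, and adjusted p = 0.266 with an estimated correlation). Of 24 mitosis genes CDK1, at least 4.13-fold lower, and PLK1 (−0.75 ± 0.21) fell and HMGB2 rose by 1.22 ± 0.33, with 5 and 1 adjusted over the list alone (0.0174, and adjusted p = 0.419 with an estimated correlation). Of 27 interferon genes 7 fell, such as OAS1 (−3.89 ± 0.52), and ISG20 rose by 1.40 ± 0.24, with 10 and 1 adjusted over the list alone (0.0186, and adjusted p = 0.171 with an estimated correlation). Of 18 fibroblast markers 5 fell, and 6 adjusted over the list alone (0.00245, and adjusted p = 0.171 with an estimated correlation). Of 13 cholesterol and lipid genes 6 fell, such as FASN, fatty acid synthase (−2.46 ± 0.32), and 8 adjusted over the list alone (1.60e-04, and adjusted p = 0.230 with an estimated correlation). Of 23 matrix genes 4 fell and 2 rose, TNC (2.63 ± 0.24) and MMP1, a collagenase (2.08 ± 0.35), with 5 and 2 adjusted over the list alone (0.0335, and adjusted p = 0.230 with an estimated correlation). Shifted up were 22 growth factors and receptors, of which 7 rose and 1 fell, FGF1 (−1.27 ± 0.28), with 8 and 2 adjusted over the list alone (0.0446, and adjusted p = 0.271 with an estimated correlation). The sizes for OAS1, MCM7, MMP1 and FGF1 depend on the floor too, and FGF1 did not pass with a higher one. The count without any 1 of the 4 arrays was 175 to 217.

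Against passage 9 (n = 2 and 2), hTERT cells of experiment I had higher TERT (4.47 ± 0.28), ATF3 (3.68 ± 0.59), PIM1 (3.61 ± 0.45, its other probe −0.62), GDF15 (3.61 ± 0.50) and MAP1B, a microtubule protein (3.39 ± 0.61). FGF2 was at least 21.7-fold, SNRPC at least 20.2-fold and the interleukin 6 receptor IL6R at least 12.1-fold higher. CCDC106 was at least 45.0-fold, SLC25A1 at least 40.0-fold, SLC1A6 at least 32.1-fold and STC1 at least 20.1-fold lower, and TCTA fell by 3.92 ± 0.95. SCARB1, a lipoprotein receptor, fell by 3.57 ± 0.48, RIN1 by 3.52 ± 0.45 and MVD, an enzyme of cholesterol synthesis, by 3.43 ± 0.65. The dimmer arm averaged under 2 times the floor for TERT, PIM1, MAP1B, TCTA, SCARB1 and RIN1, and below for MCM7, ENO2 and FAP, so their sizes depend on the floor, and TCTA did not pass with a lower one. Of the 4592 probes 276 passed, 144 higher and 132 lower, while EGFR (1.23 ± 0.59, adjusted p = 0.290), CDKN2A (1.01 ± 0.36, 0.139) and MYC (−0.07 ± 0.28 and −0.13 ± 0.53, both 0.937) did not. Of 26 lists 4 passed, all downward. Of 13 cholesterol and lipid genes 9 fell, such as HMGCS1 (−3.33 ± 0.59), IDI1 (−2.67 ± 0.39) and FASN (−2.66 ± 0.32), and 11 adjusted over the list alone (1.82e-09, and adjusted p = 0.124 with an estimated correlation). Of 31 DNA replication genes 4 fell, such as MCM7 (−3.41 ± 0.54) and MCM3 (−1.68 ± 0.28) (0.0161, and adjusted p = 0.305 with an estimated correlation). Of 10 glycolysis genes ALDOC, an aldolase (−3.05 ± 0.47), and ENO2 (−2.66 ± 0.47) fell, and 3 adjusted over the list alone (0.0154, and adjusted p = 0.124 with an estimated correlation). Of 18 fibroblast markers FAP fell by 1.78 ± 0.20, and 2 adjusted over the list alone (0.0356, and adjusted p = 0.305 with an estimated correlation). Leaving out any 1 of the arrays gave 93 to 155 probes.

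In experiment II, cells with the empty LXSN vector were compared with untransduced cells (n = 2 and 2), with the passage of neither arm stated. IFIT3, an interferon-induced gene, was at least 14.95-fold, KRT13 at least 14.1-fold and PIM1 at least 6.17-fold higher. H2BC6 rose by 3.86 ± 0.65, SERPINB3 by 3.68 ± 0.50, OAS1 by 3.52 ± 0.52, H2BC21 by 3.01 ± 0.32 and SPRR1A by 2.50 ± 0.31. G0S2 fell by 3.75 ± 0.64, NNMT fell by 3.67 ± 0.70, IL13RA2 by 2.45 ± 0.33, TGFB2 by 2.18 ± 0.36, VEGFA by 2.15 ± 0.43 and TNC by 2.08 ± 0.24. SMOX, a spermine oxidase, was at least 8.04-fold and CTH at least 4.35-fold lower. The dimmer arm averaged under 2 times the floor for H2BC6, SERPINB3, OAS1, H2BC21, IL13RA2 and TGFB2, so their sizes depend on the floor, and OAS1 did not pass with a lower floor, nor TGFB2 with a higher one. Of the 4592 probes 41 passed, 23 higher and 18 lower. EGFR (−1.82 ± 0.59, adjusted p = 0.242), CDKN2A (−0.48 ± 0.36, 0.671) and MYC (0.30 ± 0.28, 0.742, and −0.46 ± 0.53, 0.821) did not pass. Of 26 lists 3 passed, all upward. Of 27 interferon genes 5 rose, also IFI44 (2.14 ± 0.24), IFI44L (2.34 ± 0.45) and MX1 (1.32 ± 0.23), and 8 adjusted over the list alone (4.19e-07, and 0.00534 with an estimated correlation). Of 20 squamous genes 4 rose, also PI3 (2.42 ± 0.29), and 10 adjusted over the list alone (1.33e-10, and 0.00171 with an estimated correlation). Cholesterol and lipid genes passed camera (0.00216, and adjusted p = 0.462 with an estimated correlation), but limma passed 0 of the 13 (537 of all probes had an unadjusted p under 0.05). Without LXSN replicate 1, which stood apart, 16 probes passed, and without both vector arrays that stood apart 10, where the interferon and squamous lists gave adjusted p of 4.40e-07 and 1.70e-09. Without LXSN replicate 2, untransduced replicate 1 and untransduced replicate 2, the counts were 152 (51 higher and 101 lower), 24 and 3, and a fit on the arrays of experiment II alone passed 1 probe, which shared 0 with the 41 (limma, 527 at an unadjusted p under 0.05).

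Cells labelled hTERT were also compared with untransduced cells of experiment II (n = 2 and 2), again with the passage of neither arm stated. TERT was at least 50.7-fold, UFM1 at least 13.0-fold and CELF1, an RNA-binding protein, at least 5.50-fold higher. FOSL2 rose 7.98-fold, and NUP160, a nuclear pore protein, rose by 2.19 ± 0.23, RO60 by 2.05 ± 0.30, AKAP12, a kinase anchor, by 1.85 ± 0.21 and NUP98, another pore protein, by 1.60 ± 0.27. C3 was at least 37.9-fold, THBS3 at least 4.28-fold and C1S, a complement protease, at least 3.36-fold lower, and SAA1 fell by 2.21 ± 0.25. Untransduced cells averaged under 2 times the floor for NUP160 and RO60, so their sizes depend on the floor, and RO60 did not pass with a higher one. CYP2F1 (−1.48, adjusted p = 0.0513), KYNU (−1.85, 0.0518), FAP (−1.07, 0.0533) and PLAT (−2.59, 0.0593) did not pass. Nor did EGFR (0.92 ± 0.59, 0.583), CDKN2A (0.48 ± 0.36, 0.635) or MYC (0.88 ± 0.28, 0.241, and 0.51 ± 0.53, 0.748). Of the 4592 probes 18 passed, 11 higher and 7 lower. Of 26 lists 2 passed, both upward: mitosis (24 genes, 3.32e-06, and adjusted p = 0.264 with an estimated correlation), of which CDK1 rose by 1.54 ± 0.24 and 2 adjusted over the list alone, and DNA replication (31 genes, 0.0150, and adjusted p = 0.264 with an estimated correlation), of which limma passed 0 over all probes, with 562 of all probes at an unadjusted p under 0.05, and 1 adjusted over the list alone. Without hTERT replicate 1 the count was 39, 15 higher and 24 lower, without hTERT replicate 2 it was 13, 5 higher and 8 lower, and a fit on the arrays of experiment II alone passed 2.

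The passage change and the change on arrays labelled hTERT against vector were compared across probes, in experiments that share no array. The correlation was −0.313 (Pearson) and −0.241 (Spearman) over 4592 probes, which are not independent replicates. By sign alone, 27 of the 32 probes that passed as higher at passage 13 and 12 of the 14 that passed as lower ran opposite on arrays labelled hTERT. Of the probes that passed as higher at passage 13, 18 also passed as lower on arrays labelled hTERT, among them C3, FAP, OAS1, PI3, PLAT and SAA1. Of the probes that passed as lower at passage 13, 8 also passed as higher on arrays labelled hTERT, among them ASNS, CTH, PTGS2 and TNC. If probes were independent, 0.850 and 0.591 would be expected. Probes that move together break that assumption, so these expected counts are no test of chance. In the same direction 0 and 0 passed in both comparisons (limma, 1.35 and 0.372 expected). Of all probes 1106 and 409 had an unadjusted p under 0.05 in these comparisons.

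The F test of whether the change between hTERT and vector differed between experiments II, IV, VIII and XI passed 9 probes. TERT differed, higher by at least 5.66 in experiment II, where the vector arrays lay at the floor, while both arms lay at the floor in the others. C3 differed, with −4.88 in experiment II, a bound because its hTERT arrays lay at the floor, −1.14 in experiment IV, −3.06 in experiment VIII and −2.34 in experiment XI. Of all probes, 321 had an unadjusted p under 0.05. Within experiments II, IV, VIII and XI, 290, 224, 54 and 1 probes passed. In the test of experiment II against experiment IV, 10 passed, 4 higher and 6 lower.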

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

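The tests of the TERT signal were chosen after its values were seen. The change between hTERT and vector differed between experiments II, IV, VIII and XI for 9 probes by the moderated F test. TERT had an F of 88.5. Values against an arm whose arrays all lay at the floor are bounds. THBS3 (F = 39.2) gave −2.29, 1.69 and 0.17 in experiments II, VIII and XI, all bounds, and lay at the floor in both arms of experiment IV. SPRR1A (F = 37.9) gave −2.89, −1.80, −6.38 (a bound) and −0.14 in experiments II, IV, VIII and XI. The probe HG358-HT358_at (F = 36.7) gave −1.05, −0.44, 2.75 and −1.19 in the same order. COL2A1 (F = 26.1) gave −0.60, −0.40, −2.93 and 3.04, the last pair bounds. AQP3, a water channel (F = 25.5), gave −0.72, −1.29, 0.59 and −3.86 (a bound). The probe X03473_at (F = 23.1) gave 3.49, 0.07 (a bound), 2.61 and 1.45. KIAA1549L (F = 20.5) gave 1.38, −2.36, −3.05 (a bound) and −0.06. C3 had an F of 20.3. Experiments VIII and XI held 1 array per arm, so single arrays carry their values.

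TERT was bright on the hTERT arrays of experiments I and II, and under the floor on the arrays labelled hTERT of experiments IV, VIII and XI. Arms swapped in these experiments would need the changes to run opposite to those of experiments I and II, but the correlations across probes were 0.533, 0.453 and 0.254, which argues against a swap. A construct or transcript that this probe does not detect cannot be told apart from missing expression, since the highest intensity on these arrays was −250.7 and no other measure of hTERT was used here. No biological explanation was tested.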

How the results depend on the processing

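The runs without the vector arrays that stood apart, those of the passage correlation without an experiment or with passage 9 by replicate 2, the bright probes and the crossed pairing were chosen after seeing the data. For hTERT against vector (316), 301 probes passed with median scaling, 285 with trimmed means, 260 as deposited, 247 and 382 with a lower and a higher floor, 298 with a generalized logarithm, 350 without a filter, 332 with the stricter filter, 403 with a trended and robust variance and 333 without experiment XI. For hTERT against passage 13 the median change of all probes was −0.0062 in the main fit and −0.114 as deposited. For hTERT against vector it was −0.0189 in the main fit, −0.118 with trimmed means and −0.127 as deposited. The count moved to 1 with replicates averaged (877 at an unadjusted p under 0.05), 1 without experiment II (606), 0 without experiment IV (limma, 832), 133 without experiment VIII, 637 with the group as a random block, 899 with all controls, 29 by at least 2-fold in all 4 experiments and 146 without the arrays that stood apart. Leaving out an array gave 121 to 333: II hTERT replicates 1 and 2 gave 133 and 121, LXSN 195 and 161, IV BABE 196 and 203, IV hTERT replicate 2 167, and either array of experiment VIII 133. Fewer arrays remained where arrays or experiments were left out, but this cannot give the rises to 637 and 899. The random block had a consensus correlation of −0.245. The causes were not tested further.

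Leaving out an array gave 15 to 39 for passage (46; passage 13 replicates 22 and 23, passage 9 replicate 1 15), 175 to 217 for hTERT against passage 13 (491; hTERT 189 and 210, passage 13 175 and 217) and 93 to 155 against passage 9 (276; hTERT 106 and 120, passage 9 155 and 93). It gave 3 to 152 for LXSN (41; LXSN 16 and 152, untransduced 24 and 3), 13 to 39 for hTERT against untransduced (18; hTERT replicate 1 39) and 6 to 31 for the F test (9; II hTERT replicate 1 18, LXSN replicate 2 29, IV BABE replicate 2 31). With only the arrays of the experiment, counts were 846, 557, 1 (LXSN, not among the 41) and 2 (hTERT against untransduced), and LXSN gave 10 without the arrays that stood apart. Treating dim signal differently moved hTERT against untransduced to 32 (higher floor) and 9 (generalized logarithm), and the F test to 15 (lower floor), 17 (higher floor), 16 (generalized logarithm) and 25 (no filter). For hTERT against vector the share of passing probes that were higher, 61.4%, was 70.4% with median scaling and 53.3% with trimmed means. The share higher moved from 56.1% to 69.0% for LXSN as deposited, and from 61.1% to 47.6% for hTERT against untransduced with trimmed means. Leaving out an array turned it to 33.6% for LXSN (LXSN replicate 2), 38.5% for hTERT against untransduced (either hTERT array), and 38.6% and 34.0% for hTERT against passage 13 and passage 9 (hTERT replicate 1). Bright probes gave 43 for passage and 310 against passage 9.

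With the replicate number as a block, 205 passed for hTERT against vector, 137 against passage 9, and by limma 0 for passage (602 at an unadjusted p under 0.05), 0 for LXSN (498) and 0 for hTERT against untransduced (511). A crossed pairing gave 2 for passage. Deviations of same-numbered replicates correlated by 0.109, −0.105 and −0.298 in experiment I, 0.0354, 0.00335 and −0.0546 in experiment II and 0.0135 in experiment IV. These values give no clear sign that the numbers pair the arrays. No chance value was set beside them, so a batch shared by some arrays cannot be excluded.

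Of the lists, 7 passed for hTERT: 3 without experiment II, 4 with all controls, 0 with an estimated correlation (fry 10), and 5 to 8 leaving out an array. For passage 10 passed, 3 with an estimated correlation, and 7 to 11 leaving out an array. The correlation of the passage effect against hTERT effect, −0.313, was −0.244, −0.355, −0.299 and −0.294 without experiments II, IV, VIII and XI, −0.185 with passage 9 by replicate 2 and −0.313 without the arrays that stood apart, none of them under a share of 0.05 of the splits, partly because fewer splits remained. Values that reversed were not past the threshold, and are given with their range on leaving out an array. The MYC probe M13929_s_at reversed against passage 9 without hTERT replicate 1 (0.022, range −0.29 to 0.022) and against passage 13 without hTERT replicate 2 (−0.13, range −0.13 to 0.19). The MYC probe L00058_at reversed against passage 13 without passage 13 replicate 2 (−0.0051, range −0.0051 to 0.29), and CDKN2A with passage without passage 13 replicate 2 (−0.11, range −0.11 to 0.56). Among genes named for arrays labelled hTERT against vector, 727 results kept their side, 106 lost and 7 gained the threshold and 0 reversed; COL11A1 lost it in 12, SPRR1A in 15, OAS1 in 11 and NNMT in 8 of 30 settings. For passage KRT13 lost it in 10, PDE7A in 13 and ENO2 in 8 of 15 settings and PTGS2 in 7 of 16. For LXSN NNMT, SMOX and VEGFA lost it in 9, KRT13 in 8 and IFIT3 in 7 of 15. For hTERT against untransduced C1S and NUP98 lost it in 9 and FOSL2 in 8 of 14, against passage 9 SNRPC in 7 of 14 and TCTA in 7 of 15, and against passage 13 EGFR in 5 of 14.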

Other observations

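The list of amino acid response genes was written after ASNS, CTH, CBS, ATF3 and VEGFA had been seen, and the tests of the passage correlation were chosen after it was seen, except that of hTERT against untransduced cells. The correlation of the LXSN change with that on arrays labelled hTERT and the splits with arms kept together were also chosen after the data were seen. Genes that respond to amino acid shortage were higher on arrays labelled hTERT. All 20 measured genes of the list, those seen first included, were higher than with empty vector (n = 6 and 6), with a median of 1.28, and 14 passed. The 15 that had not been seen were measured on the same arrays as the genes that prompted the list. The estimated correlation was 0.156 among them and 0.197 over all 20, so their rise is no separate evidence. For these 15, camera gave an adjusted p of 7.40e-10, and 0.0115 with an estimated correlation. Of these, 9 rose: CEBPG, a transcription factor (1.63), the aminoacyl-tRNA synthetases AARS1 (1.35), YARS1 (0.96), EPRS1 (0.84) and WARS1 (0.64), the serine and folate enzymes PSPH (1.29), SHMT2 (1.29) and MTHFD2 (1.28), and the glutamine transporter SLC1A5 (0.86). For the 15 unseen genes, the median at passage 13 against passage 9 was −0.40, with 14 lower (adjusted p = 0.0114 with an estimated correlation) and by limma 0 past the threshold (409 of all probes at an unadjusted p under 0.05). With LXSN against untransduced cells all 15 were lower, with a median of −0.76 (0.00728). The LXSN arrays are also the vector arm of experiment II, so opposite signs against the rise over vector are partly built in. The same holds for the passage 13 arrays, shared by the passage comparison and that of hTERT against passage 13. The median was 0.80 for hTERT against passage 13 (0.0168), 0.18 against passage 9 (0.307) and 0.38 for hTERT against untransduced cells of experiment II (0.0801), so the last comparisons did not pass with an estimated correlation.

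A wider rise of amino acid response genes is a hypothesis that may cover ASNS, CTH and ATF3, since the median of the 15 unseen genes was 0.864. The vector arrays that stood apart do not account for the rise of all 20 listed genes, those seen first included. Their median was 1.15 without these arrays and 1.28 with them. Nor does the scaling, with a median of all listed genes 1.34 above that of all probes under median scaling. These values are not given here for the 15 unseen genes alone. Lower values in the vector cells may carry part of the difference. In experiment II the 15 unseen genes had a median of −0.76 for LXSN against untransduced cells, and 0.38 for hTERT against untransduced cells. Experiments IV, VIII and XI held no untransduced cells, so a fall with vector and a rise with hTERT cannot be told apart there. Whether the medium differed between arms was not tested.

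By at least 2-fold in the same direction in all 4 experiments, 29 probes stood out, 16 higher and 13 lower, where the highest of the other splits gave 6. Named after their values were seen, they included the probe HG2724-HT2820_at (5.29 ± 0.31), GATA6, a transcription factor (1.86 ± 0.20), CCNA1, a cyclin (1.60 ± 0.17), CCDC85B (1.60 ± 0.20), H1-10, a linker histone (1.32 ± 0.23), CD47, a surface protein (−1.73 ± 0.20), RAB40B (−1.69 ± 0.21) and PPBP, a chemokine (−1.41 ± 0.21). The dimmer arm averaged under 2 times the floor for that probe, GATA6, CD47, RAB40B and PPBP, so their sizes depend on the floor. For LXSN against untransduced cells of experiment II, HG2724-HT2820_at fell by 5.48 (limma, adjusted p = 0.0212). PPBP rose there by 2.03 (limma, adjusted p = 0.0394), but did not pass with a lower floor. The differences of these 2 probes in experiment II thus lay at least partly in the LXSN arm. For the count of 316 probes, 1 of 72 splits of the 12 arrays within experiments, the real one, gave as many, and the highest other gave 0, which excludes chance only if the replicates were separate cultures, as the labels do not state. With the arrays of an arm kept together in each experiment, the 8 splits are too few for a share under 0.05 (real 316, highest other 0).

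Across probes, the change on arrays labelled hTERT tended to run opposite to that with passage. Not all lists followed, as the cholesterol and lipid list was shifted down in both comparisons. Chance cannot be firmly excluded: by Pearson correlation 3 of 72 splits were as large as the real −0.313, a share under 0.05, but the highest other, 0.344, exceeded it, and by Spearman 5 of 72 were (real −0.241, highest other 0.280). The limits of the table by passage 9 replicate 1 may carry part of it. The correlation stayed negative, at −0.185 with replicate 2 alone and −0.289 with replicate 2 and bright probes. The first was not under a share of 0.05 of the splits, and no share is given for the second. These values thus cannot tell whether those limits account for all of it. Without the vector arrays that stood apart the correlation was −0.313. The change of LXSN against untransduced cells and that of arrays labelled hTERT against vector in experiments IV, VIII and XI, which share no array, correlated by −0.391, where 12 splits are too few for a share under 0.05 (highest other 0.372; by Spearman −0.358 and 0.364). Since the passage of neither arm is stated, vector cells further along the passage change than untransduced cells cannot be told apart, with correlations of 0.167, 0.150 and 0.0603 for LXSN. That hTERT cells were less far along than untransduced cells goes with correlations of −0.236, −0.236 and −0.202. The second repeats the first because its setting leaves out no array of that comparison. The mitosis list goes the other way: by camera at the preset correlation it was shifted up with passage and with hTERT against untransduced cells. Differing passages stay open in these hTERT comparisons too.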
